A study of Bos taurus with 48 samples.

How the data were processed

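Total RNA from calf liver, mammary parenchyma and mammary fat pad was depleted of ribosomal RNA and sequenced as paired reads of 150 cycles, with all libraries in 1 pool, per the labels' protocols. Each deposited table holds HTSeq read counts for 27607 cattle genes with Ensembl identifiers, followed by 5 summary entries for reads that were not assigned to a gene. STAR 2.7.8, HTSeq 1.99.2, FastQC and DESeq2 are named, with the genome build ARS-UCD1.2, per the submitters' processing notes. The strand setting and multi-read setting of the counting are not given in the sources used here, so reads of overlapping and antisense genes cannot be separated, and genes with near-identical copies are uncertain. The deposited counts were used without any change of unit.

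The labels place 48 samples in 9 groups of tissue by diet. Of these, 47 had counts that were used, and the parenchyma control sample numbered 2, whose title carries the abbreviation PAD, was not analysed here. Groups were taken from the tissue and diet fields. The titles of the fat pad control samples numbered 1 and 2 carry the abbreviation PAR, which the series title uses for parenchyma, and these libraries were kept as fat pad controls in the main comparisons. The labels do not say whether samples with the same number come from the same calf, nor that each library of a group is a separate calf, so p-values measure the spread between these samples.

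The summary entries stayed out of library sizes and tests. Counts assigned to genes totalled 5.59 to 24.2 M (mega, by the metric prefix) per library, with a median of 13.8 M. Reads outside annotated features made up 53.0% to 78.0% of uniquely placed reads, and 21.7% to 46.4% were assigned to genes, the share used as a covariate. Reads aligned to more than a single place made up 5.74% to 14.9%. Only 2 libraries had reads in the entry for unaligned reads, liver control 1 with 16 M and fat pad control 1 with 14.4 M. They were also the 2 libraries of lowest depth.

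The files do not pair gene identifiers with names, and a RefSeq table of a different assembly matched 0 of the identifiers. Genes are therefore given by identifier, with at most 2 that rose and 2 that fell for a comparison. The comparisons, their tests, the first group of alternatives, 33 gene lists, a marker check of the tissues, a marker-score covariate and the rule for naming genes were fixed before the data were examined. The lists, the marker check and the marker-score covariate could not be run without names. The naming rule took the called genes of lowest p with a mean log2 CPM of 1 or more and a symbol. It yielded no name, so the identifiers printed follow the same order without the symbol. Gene coordinates were not used here.

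Differential expression was tested with edgeR 4.0.16 in R 4.3.3, using TMM factors, filterByExpr (minimum count 10, minimum total 15), robust dispersion and the quasi-likelihood F test. Each comparison of diets was fitted on its 2 groups alone. The contrast of parenchyma with fat pad was the mean over the 3 diets in a fit of 6 groups, and differences of the diet effect between tissues were interaction contrasts in fits of 4 groups. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, over all genes tested in the comparison. Levels are CPM, read counts per M counts, on TMM-scaled library sizes of all 47 libraries, and log2 CPM used a prior count of 2. Errors of log2 fold changes are standard errors from the F statistic.

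The position of a mammary library was its projection on the difference between the parenchyma mean (0) and the fat pad mean (1) of the restricted and unlimited libraries over 17744 genes, leaving the library itself out of the means. As a covariate, position was used in this form and in a form computed against the parenchyma controls in place of the restricted and unlimited parenchyma. Library measures were compared with two-sided exact permutation tests of the difference in means, adjusted over 33 tests. After the data were seen, the mean of the restricted and unlimited diets was compared with control in liver and parenchyma, and genes were put in classes by tissue from the restricted and unlimited libraries. Liver genes had a mean log2 CPM at least 2 above both mammary tissues. Parenchyma and fat pad genes were the others that differed between these tissues by at least 1. Classes and other sets were tested with limma 3.58.1 camera on voom values, with a preset inter-gene correlation and with an estimated correlation, and with fry.

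The count tests were first tested on simulated data with negative binomial counts for the real genes and 200 genes changed 1.5-fold, 2-fold or 4-fold. For parenchyma of unlimited against restricted calves, with 13962 simulated genes tested, 31.8%, 71.2% and 96.9% of these were recovered, with 7 false among 138 calls. For liver, with 13750 genes, the shares were 9.23%, 48.4% and 93.7%, and for fat pad, with 15040 genes, 34.8%, 55.2% and 90.8%. With 15486 simulated genes in fat pad of restricted against control calves, 0%, 7.69% and 60.0% were recovered.

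Alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma voom with sample quality weights, other filters on low counts, a fold change minimum, all 3 diets in the fit, each library or number left out, and the PAR-titled libraries left out or moved to parenchyma. A covariate for the share of reads assigned, thinning to the smallest library, covariates for position, the tissue contrast without controls and fat pad controls without numbers 18 and 21 were added after seeing the data. The 105 pairs of replicates were compared over genes with at least 20 counts in a pair, and chi-square per gene ranged from 15.8 to 494, with 0 identical pairs, so every library was counted as a separate sample.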

Results

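Gene expression was measured by RNA sequencing in liver, mammary parenchyma (the epithelial part of the developing gland) and mammary fat pad (the adipose bed into which it grows) of dairy calves on 3 feeding levels. Control calves received a standard ration, restricted calves a reduced daily ration of milk replacer, and unlimited calves milk replacer without limit in 3 meals of 30 minutes a day. Restricted and unlimited groups had 6 libraries in each tissue. Control groups had 4 libraries in liver, 4 in fat pad and 3 in parenchyma. Total gene counts ranged from 5.59 to 24.2 M per library.

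The first question was whether libraries fell by tissue as labelled. On a scale from the parenchyma mean at 0 to the fat pad mean at 1, the 12 fat pad libraries of restricted and unlimited calves lay between 0.808 and 1.09. Parenchyma libraries of all 3 diets lay between -0.021 and 0.0744. The libraries labelled fat pad control did not lie with the other fat pad libraries: numbers 1, 2, 21 and 18 were at -0.0312, 0.0276, 0.123 and 0.536. Numbers 1 and 2 carry PAR in their titles, while numbers 18 and 21 do not. The mean position of the 4 was 0.164 ± 0.256 (SD, n = 4) against 0.999 ± 0.0691 in restricted fat pad (n = 6), an exact permutation p of 0.00476, the smallest this design can give, and 0.0524 after adjustment over 33 tests of library measures. Library 18 also had 86 genes at 8 times or more the level of every other library, against at most 2 such genes in any other library.

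**Figure D1:**
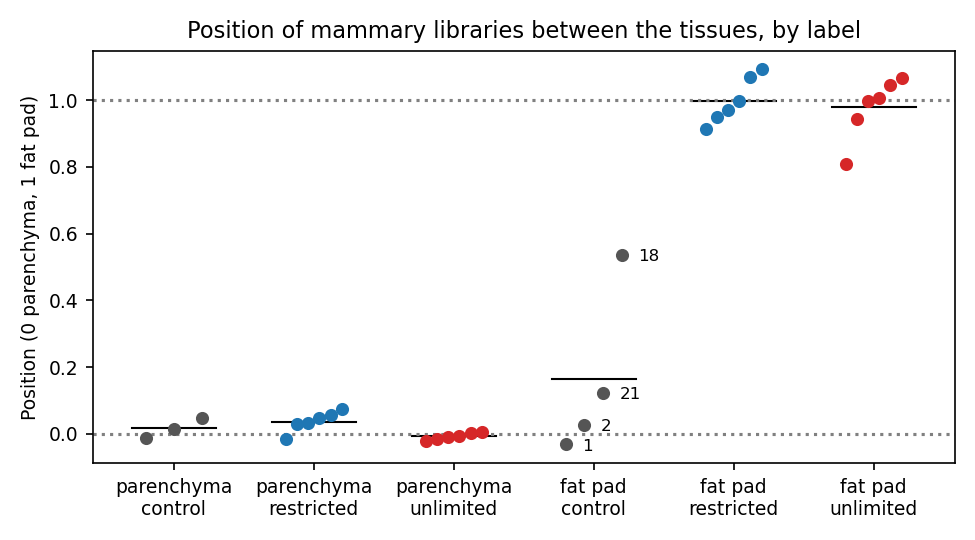
Position of each mammary library between the parenchyma mean (0) and the fat pad mean (1) of restricted and unlimited libraries, by label; points are libraries, lines are group means, and digits beside the fat pad control points are sample numbers. Libraries labelled fat pad control lie between -0.0312 and 0.536, and the other fat pad libraries between 0.808 and 1.09.

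Parenchyma and fat pad differed in 9032 of 17195 genes over the 3 diets, 4258 higher in parenchyma and 4774 higher in fat pad. At least 4-fold differences were more frequent on the fat pad side, with 1144 genes against 473. ENSBTAG00000000253 was at 234 ± 32.2 CPM (SD, n = 6) in restricted fat pad and at 24.3 ± 3.70 CPM (n = 6) in restricted parenchyma. Its log2 difference over all diets was -2.47 ± 0.11 (SE, edgeR adjusted p = 7.16e-16), and its level in the libraries labelled fat pad control was 32.3 ± 9.11 CPM (n = 4). ENSBTAG00000009065 was higher in parenchyma, with a log2 difference of 1.78 ± 0.10 (edgeR adjusted p = 4.41e-14) and 131 ± 20.1 CPM against 21.7 ± 2.38 CPM in restricted calves. Its level in the libraries labelled fat pad control was 80.5 ± 30.5 CPM (n = 4). The contrast over all diets counts these libraries as fat pad, which lessens the log2 differences of both genes. In libraries of restricted and unlimited calves alone, 10649 genes were called.

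**Figure D2:**
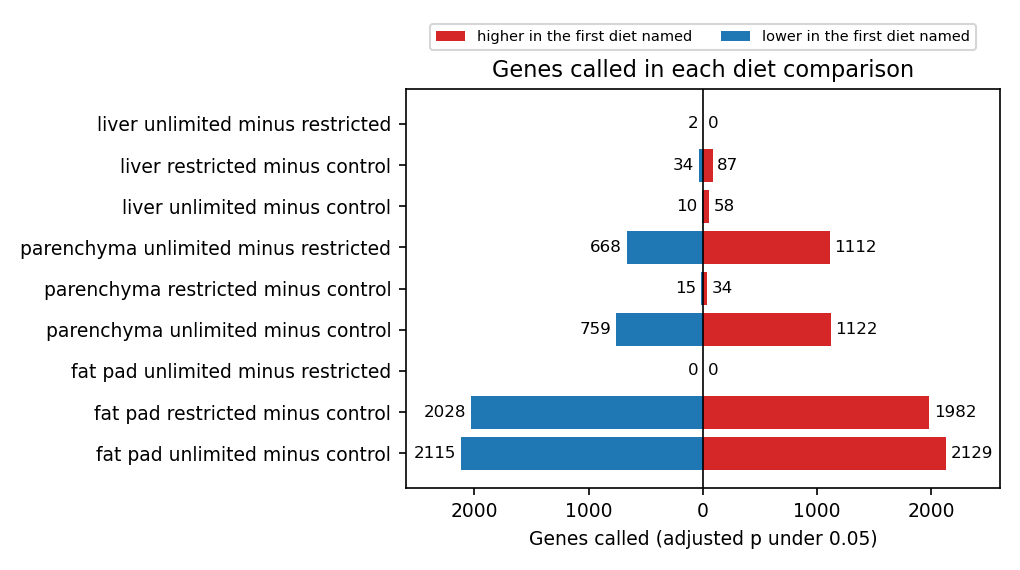
Number of genes called by edgeR in each comparison of diets, higher to the right and lower to the left of 0, for the first diet named against the second. Parenchyma of unlimited against restricted calves gave 1112 higher and 668 lower genes, while liver gave 2 and fat pad 0; the fat pad comparisons with control rest on 4 libraries, of which 3 lie at a position under 0.25.

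In parenchyma, feeding milk replacer without limit was compared with feeding it at a reduced ration. Of 14117 genes tested, 1112 were higher and 668 lower in unlimited calves, with a median absolute log2 fold change of 0.661. Most changes were moderate, and 278 higher and 116 lower genes changed at least 2-fold. ENSBTAG00000005069 rose 5.11-fold, from 3.06 ± 0.584 to 15.9 ± 2.38 CPM (SD, n = 6 each), with a log2 fold change of 2.35 ± 0.17 (SE, edgeR adjusted p = 3.95e-06). ENSBTAG00000005989 rose from 70.7 ± 11.7 to 164 ± 11.6 CPM, a log2 fold change of 1.19 ± 0.11 (edgeR adjusted p = 8.18e-05). ENSBTAG00000053310 fell from 20.3 ± 5.59 to 5.76 ± 1.55 CPM (edgeR adjusted p = 0.000459), and ENSBTAG00000006255 fell from 55.6 ± 6.49 to 33.9 ± 2.27 CPM (edgeR adjusted p = 0.00113). Of the called genes, 660 had no overlap between the 2 diets, and 721 of all tested genes did, where chance gives 0.216%. Genes of the parenchyma class were called most often, 327 higher and 62 lower among 1878 tested, or 20.7% of the class. The share was 12.6% over all tested genes and 13.6% in the liver class. The classes were set by level in these same libraries, and whether detection differs between classes was not tested. Among 1431 genes of the fat pad class, 32 were higher and 63 lower. The parenchyma class rose relative to other genes with camera's preset correlation (adjusted p = 0.00139 over 18 tests) but not with an estimated correlation (adjusted p = 0.353). Fry, which does not set the class against other genes, gave an adjusted p of 0.0203 for its rise. Position towards fat pad was -0.00644 ± 0.0108 in unlimited and 0.0373 ± 0.0310 in restricted parenchyma (SD, n = 6 each, exact permutation p = 0.0130, adjusted p = 0.1). With the share of assigned reads as a covariate, chosen after seeing the data, 765 genes were called, and 744 of them were among the 1780. With position as a covariate, also chosen after seeing the data, 3 were called, ENSBTAG00000005069, ENSBTAG00000005989 and ENSBTAG00000053310, and ENSBTAG00000006255 did not pass. Without restricted library 16, unlimited library 15 or unlimited library 11, the counts were 1029, 1131 and 1083.

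**Figure D3:**
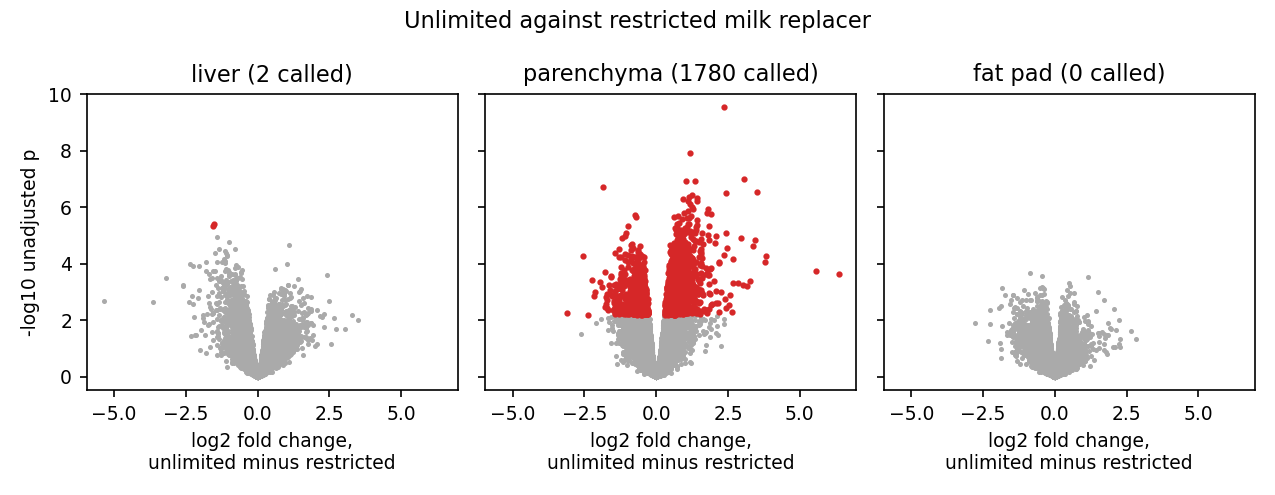
Log2 fold change of unlimited minus restricted calves (horizontal axis) against -log10 of the unadjusted edgeR p (vertical axis) for each tested gene in liver, parenchyma and fat pad, with called genes in red. Parenchyma has 1780 called genes, liver 2 and fat pad 0.

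Fat pad gave no called gene for the same diets. Of 15203 genes tested, 0 passed in edgeR, with a lowest adjusted p of 0.541. At an unadjusted p under 0.05 there were 1316 genes, where 760 would be met by chance. DESeq2 called 3 genes and limma voom with quality weights 0. The share of reads assigned was 41.0% ± 3.23 in unlimited and 34.6% ± 4.61 in restricted fat pad (SD, n = 6 each, exact permutation p = 0.0152, adjusted p = 0.1).

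Liver of unlimited against restricted calves gave 2 called genes, both lower in unlimited calves. ENSBTAG00000001303 fell from 41.5 ± 9.71 to 14.2 ± 4.56 CPM and ENSBTAG00000012128 from 66.2 ± 21.4 to 22.1 ± 3.82 CPM (SD, n = 6 each), with log2 fold changes of -1.53 ± 0.22 and -1.55 ± 0.22 (SE, edgeR adjusted p = 0.033 for both). The 1236 genes of the liver class had a median log2 fold change of -0.23. As a set they fell relative to other genes with camera's preset correlation (adjusted p = 8.82e-11) but not with an estimated correlation (adjusted p = 0.233). Fry's adjusted p for the fall was 0.0407. Unlimited libraries 3 and 6 had TMM factors of 0.932 and 0.942. Those of the remaining unlimited libraries were 0.734 to 0.799, and those of restricted liver 0.679 to 0.798. Whether the fall of the class rests on libraries 3 and 6 was not tested. At an unadjusted p under 0.05 there were 1984 of 14030 genes against 702 by chance, and DESeq2 called 356 genes and limma voom with quality weights 110. With the share of assigned reads as a covariate, chosen after seeing the data, edgeR called 0 genes, and that share was 30.9% ± 4.94 in unlimited and 36.5% ± 4.22 in restricted liver (SD, n = 6 each, exact permutation p = 0.0649, adjusted p = 0.268). The edgeR count rested on single libraries: it was 237 without restricted library 8, 26 without unlimited library 11, 4 without unlimited library 9, and 0 without restricted libraries 4, 5, 10, 13 or 16 or unlimited libraries 3, 7 or 15, each left out alone.

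Whether the response to these diets differed between tissues was tested as an interaction. Between parenchyma and fat pad it differed for 125 of 16077 genes, 98 with a more positive and 27 with a more negative change in parenchyma, and DESeq2 called 478 and limma voom with quality weights 375. ENSBTAG00000005069 was at 5.39 ± 0.391 CPM in restricted and 5.25 ± 1.23 CPM in unlimited fat pad (SD, n = 6 each), and the difference of its log2 fold changes was 2.42 ± 0.23 (SE, edgeR adjusted p = 1.3e-06). ENSBTAG00000055062 fell in parenchyma relative to fat pad, by a difference of -0.59 ± 0.09 (edgeR adjusted p = 0.00426). Between parenchyma and liver, 1158 of 15629 genes differed, 815 with a more positive and 343 with a more negative change in parenchyma, and DESeq2 called 1808. In liver, ENSBTAG00000005069 was at 308 ± 105 CPM in restricted and 172 ± 54.2 CPM in unlimited calves (n = 6 each). Between fat pad and liver edgeR called 0 of 16228 genes, with 2122 at an unadjusted p under 0.05 where 811 would be met by chance, and DESeq2 called 157 and limma voom with quality weights 6. For parenchyma and fat pad the count was 41, 31, 50, 37, 55, 269, 20 and 28 without number 4, 5, 6, 7, 9, 10, 15 and 16. For parenchyma and liver it was 589, 608, 712, 717 and 768 without number 4, 5, 6, 15 and 16, and for fat pad and liver 48 without number 8 and 8 without number 11.

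Parenchyma of restricted calves gave 49 called genes against parenchyma of control calves. Of 14881 genes tested, 34 were higher and 15 lower in restricted calves, and 2165 had an unadjusted p under 0.05, where 744 would be met by chance. ENSBTAG00000004720 rose from 56.1 ± 8.77 (SD, n = 3) to 168 ± 14.4 CPM (n = 6), with a log2 fold change of 1.61 ± 0.15 (SE, edgeR adjusted p = 0.00166), and ENSBTAG00000007700 fell from 250 ± 10.9 to 78.6 ± 21.5 CPM (edgeR adjusted p = 0.00876). DESeq2 called 650 genes, and edgeR 198 with the PAR-titled libraries counted as parenchyma. The count was 2 without control library 21, 29 without control library 18, 9 without restricted library 4, 5 or 13, 8 without restricted library 16 and 316 without restricted library 8, and the fall of ENSBTAG00000007700 did not pass without control library 21 (edgeR adjusted p = 0.0903, against 1.72e-09 to 0.0321 under the other alternatives).

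Parenchyma of unlimited against control calves gave 1122 higher and 759 lower genes of 15119. ENSBTAG00000005069 was at 2.05 ± 0.574 CPM in controls (SD, n = 3), a log2 fold change of 2.95 ± 0.24 (SE, edgeR adjusted p = 0.000185). ENSBTAG00000046768 was at 13.2 ± 4.13 CPM in controls and between 0 and 0.399 CPM in the 6 unlimited libraries (edgeR adjusted p = 0.000146). Of 1984 genes of the parenchyma class, 405 were called higher and 135 lower. The class was defined with the unlimited and not the control libraries, which favours genes raised in unlimited parenchyma, so these counts and the test of the class are not independent evidence of its direction. Camera's adjusted p for the class was 0.000213 with the preset and 0.233 with an estimated correlation, and fry's was 0.0103. Without control library 18 the count was 907.

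Liver of calves on either of the other diets differed from control liver mostly by genes that were higher outside control. Restricted calves had 87 higher and 34 lower genes of 14238, and unlimited calves 58 higher and 10 lower genes of 14114. DESeq2 called 539 and 276 genes and limma voom with quality weights 61 and 35. ENSBTAG00000010841 rose from 155 ± 18.6 (SD, n = 4) to 551 ± 86.0 CPM (n = 6) in restricted calves, a log2 fold change of 1.79 ± 0.17 (SE, edgeR adjusted p = 0.000993), and ENSBTAG00000016738 fell from 25.8 ± 6.15 to 6.00 ± 2.06 CPM (edgeR adjusted p = 0.00663). In unlimited calves ENSBTAG00000048508 rose from 14.8 ± 2.74 to 85.8 ± 32.2 CPM (edgeR adjusted p = 0.00218), and ENSBTAG00000012128 fell from 58.4 ± 19.6 to 22.1 ± 3.82 CPM (edgeR adjusted p = 0.0109). Of the higher genes, 47 of 87 and 48 of 58 belonged to the fat pad class, which made up 1538 of 14238 and 1514 of 14114 tested genes. As a whole that class had median log2 fold changes of 0.04 and 0.1, with camera's adjusted p at 0.156 and 0.00326 with the preset and at 0.478 and 0.353 with an estimated correlation. Fry's adjusted p was 0.37 and 0.19. Control liver had fewer counts than restricted liver, 5.59 to 12.1 against 12.9 to 17.4 M (exact permutation p = 0.00476 for the mean, the smallest possible, adjusted p = 0.0524), and a lower share of assigned reads, 28.5% ± 5.28 against 36.5% ± 4.22. With that share as a covariate, chosen after seeing the data, edgeR called 0 genes for restricted against control, with 920 at an unadjusted p under 0.05, and 50 for unlimited against control. For restricted calves the count was 33, 66, 48 and 80 without control library 1, 2, 18 and 21, and 36, 42, 195, 19 and 42 without restricted library 4, 5, 8, 13 and 16. For unlimited calves it was 31, 31 and 21 without control library 1, 2 and 21, and 33, 34, 20 and 22 without unlimited library 3, 7, 9 and 11.

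**Figure D4:**
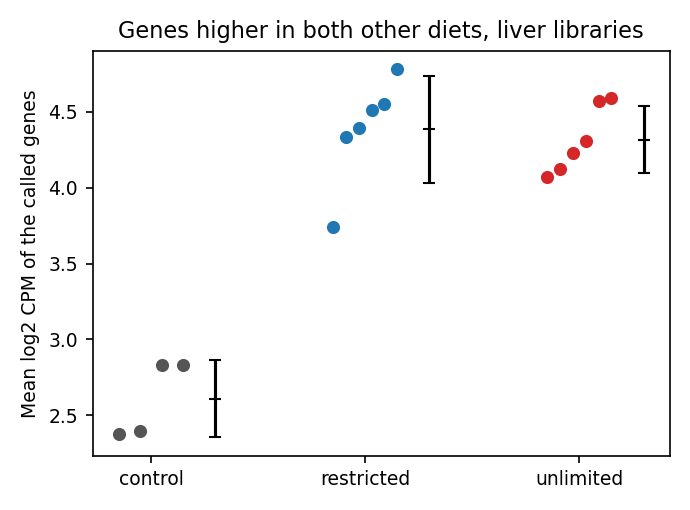
Mean log2 CPM of the 117 genes called higher in the mean of the restricted and unlimited diets than in control, for each liver library; points are libraries and bars the mean ± SD of a diet. The genes were chosen on these libraries, which lie between 2.38 and 2.83 in control and between 3.74 and 4.78 in the other diets.

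The library set labelled fat pad control differed from fat pad of both other diets in more genes than any other comparison of diets, 1982 higher and 2028 lower of 15712 in restricted calves and 2129 higher and 2115 lower of 15441 in unlimited calves. These counts compare libraries that lie at positions from -0.0312 to 0.536 with libraries at 0.808 to 1.09. Of the called genes, 96.4% in restricted and 97.6% in unlimited calves changed in the direction of the difference between fat pad and parenchyma in libraries of the remaining diet. Across 17744 genes, which are not independent replicates, the correlation with that difference was 0.853 and 0.879. ENSBTAG00000005596 was at 1.83 ± 0.26 CPM (SD, n = 4) in libraries labelled fat pad control and at 80.6 ± 16.9 CPM (n = 6) in restricted fat pad, and ENSBTAG00000025441 at 919 ± 155 and 133 ± 18.0 CPM. ENSBTAG00000019448 was at 0.329 ± 0.113 and 97.9 ± 14.1 CPM in unlimited calves. Without control library 18 the counts were 6284 and 6973, and without the PAR-titled libraries 2956 and 3594.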

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

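The tests of the fat pad control positions, of library 18, of fat pad tissue in parenchyma, of fat pad RNA in liver and of the assigned share in liver were chosen only after the results were seen, as were the comparisons of the other diets together with control, while the assigned-share test in parenchyma and the thinning tests were chosen after seeing the data but before their own results.

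A library far from the rest of its group was found for 1 of 29 groups of library measures and for 6 of 52 groups of gene levels, where chance gives about 1 in 20. The total of parenchyma restricted 5 was 17.2 M, against 9.70 to 11.8 M in the rest of its group. ENSBTAG00000048508 was at 150 CPM in liver unlimited 15 (others 64.3 to 81.6), and ENSBTAG00000053310 at 30.9 CPM in parenchyma restricted 10 (others 15.2 to 20). ENSBTAG00000004720 was at 140 CPM in parenchyma restricted 4 (others 168 to 178), and ENSBTAG00000046768 at 0.399 CPM in parenchyma unlimited 3 (others 0 to 0.122). ENSBTAG00000014698 was at 9.08 CPM in fat pad unlimited 15 (others 13.9 to 16.6), and ENSBTAG00000050189 at 5.38 CPM in liver unlimited 11 (others 9.69 to 11.7). The effect of the unlimited against the restricted diet differed between parenchyma and fat pad for 125 genes and between parenchyma and liver for 1158 genes, by the interaction test.

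Of the 4 libraries labelled fat pad control, 3 lay next to parenchyma and library 18 at a position of 0.536. Position is a projection, so it does not show how far library 18 lay from the line between the tissues. The 4010 and 4244 genes called against these 4 libraries were each matched by 1 of 100 splits, the real one. The highest of the other splits gave 366 and 1175 genes. A swap within number 2, whose fat pad control title carries PAR and whose parenchyma control title carries PAD, was not tested, as the latter was not analysed here; a swap within numbers 18 and 21 is argued against by their parenchyma control libraries, the highest of which lay at 0.048, and a mixture of the 3 tissues cannot give the 86 genes that library 18 held at 8 times or more the level of every other library. Parenchyma tissue in these libraries is a candidate explanation, as their median position was 0.0754 with 3 of 4 under 0.25. A change of the fat pad by the control diet cannot be told apart from it by position alone, since all control libraries carry that diet. For numbers 1 and 2 the PAR titles also point to parenchyma tissue. Their positions were -0.0312 and 0.0276, where parenchyma libraries lay between -0.021 and 0.0744. The 4 positions spread over a range 2 times that of the other fat pad libraries (0.567 against 0.284). That range rests on library 18, as numbers 1, 2 and 21 lay between -0.0312 and 0.123, so it does not argue against a diet change. What sets library 18 apart was not tested, and the counts against fat pad control are read here only as differences between libraries.

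The 1780 genes called in parenchyma between the unlimited and restricted diets were matched by 1 of 100 splits, the real one, with 3 genes as the highest of the others, and depth is argued against by thinning, which left 0.949 of the count. The share of assigned reads as a covariate left 0.949 of the median absolute log2 fold change (0.627 against 0.661, standard error 0.17 against 0.16), every called gene kept its sign, 765 genes passed, and why fewer passed was not tested. Position, which differed between the diets (0.0373 in restricted, -0.00644 in unlimited), left a median of 0.501 with a standard error of 0.21 as a covariate. Every called gene kept its sign and 3 genes passed, so the number of calls depends on this covariate. It was computed from restricted and unlimited libraries over genes that include the called ones, so it may carry the diet difference itself. The loss of calls thus cannot separate tissue position from diet. Position against the parenchyma controls hardly differed (0.115 and 0.11) and cannot test this (1829 genes). Fat pad tissue as the whole cause is argued against by 33 abundant fat pad genes. Their excess in restricted parenchyma had an upper quartile of 1.53% of the fat pad level. The median higher gene would need 39.8%, and 63 lower genes of the fat pad class had a lower quartile of 12.3%. Both the higher and the lower genes were called on these same libraries, which favours large values in them. Of the 1780 called genes, 285 changed against the direction that fat pad tissue in restricted parenchyma would give, and the others changed with it. That direction was taken in part from the unlimited parenchyma libraries themselves, which favours such a match. A response of parenchyma to the diet may account for the genes as a hypothesis, and a shift in the mix of cell types along with position, and handling that followed the diet, for which the labels give no batch, stay open and untested.

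In liver, 117 genes were called higher and 41 lower in the restricted and unlimited diets together than in control, a count of 158 that 1 of 100 splits gave, the real one, with 98 as the highest of the others, and thinning, which left 0.826 of the restricted against control count, argues against depth. The share of assigned reads as the whole cause is argued against by median log2 fold changes of 1.04 times those without the covariate for the diets together (1.73 against 1.67, standard error 0.37 against 0.34, 55 of 117 passing) and of 0.952 times for restricted against control (1.59 against 1.67), where the share differed most, but there the standard error was 0.42 against 0.3 and edgeR called 0 genes in place of 121, with 920 at an unadjusted p under 0.05. Fat pad RNA is argued against by 16 abundant fat pad genes, whose rise in liver had an upper quartile of 0.392% of the fat pad level. The lower quartile was 19.9% for 83 of the called genes, which were chosen on these same libraries, and this favours a large rise. Of the 117 genes, 112 were tested in parenchyma and 98 were higher there, with a median log2 fold change of 1.2. There 36 were called higher and 0 lower, where 470 of 15529 genes were called higher in all, and fry's p was 0.00502. Relative to other genes camera's p was 1.74e-18 with the preset and 0.0505 with an estimated correlation. A rise of the whole set beyond other genes thus stays open, and the bound set beforehand, a p over 0.05, was passed by too little to exclude it. An effect of the control diet may account for the genes, and handling of the control libraries, for which the labels give no batch, stays open.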

How the results depend on the processing

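The assigned-share and position covariates, thinning, the tissue contrast without controls and the fat pad comparisons without control 18 and 21 were chosen after seeing the data. Not run, for want of gene names, were the marker-score covariate and the gene list tests. For the 13 comparisons, 24 pairs of a named gene and its comparison were followed through the alternatives, which gave 485 values: 463 kept their direction and passed, 22 kept their direction without passing, in 6 of the pairs, and 0 turned. DESeq2's test gave 356, 539 and 276 genes in liver (unlimited against restricted, restricted against control, unlimited against control), 650 in parenchyma of restricted against control, 3 in fat pad of unlimited against restricted, and 478, 1808 and 157 for the interactions of parenchyma with fat pad, parenchyma with liver and fat pad with liver. Limma voom with quality weights gave 110, 61 and 35 in liver, 77 in parenchyma of restricted against control, and 375 and 6 for the interactions of parenchyma with fat pad and fat pad with liver. Without a filter the counts were 16 in liver of unlimited against restricted, 101 in parenchyma of restricted against control and 76 for parenchyma with fat pad. A log2 fold change of 1 or more left 394 and 827 genes in parenchyma of unlimited against restricted and against control, 2776 in fat pad of unlimited against control, 3803 between parenchyma and fat pad, and 73 and 643 for the interactions of parenchyma with fat pad and with liver, as it removes genes. With the assigned share as a covariate edgeR called 0 genes in liver of unlimited against restricted, 0 in liver of restricted against control, 765 in parenchyma of unlimited against restricted and 121 in parenchyma of restricted against control, where unadjusted counts without it were 1984, 1907, 4173 and 2165. Position as a covariate gave 3 in parenchyma of unlimited against restricted. Thinning gave 11 in liver of unlimited against restricted. All 3 diets in the fit gave 240, and the PAR-titled libraries counted as parenchyma 198, in parenchyma of restricted against control. Fat pad of unlimited against control gave 6689 without control 18 and 21. Except where the fewer genes are by construction, the cause was not tested.

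Leaving out 1 library at a time gave 0 (without restricted 4, among others) to 237 (without restricted 8) genes in liver of unlimited against restricted, 19 to 195 (without restricted 13 and 8) of restricted against control, and 20 to 67 (without unlimited 9 and 6) of unlimited against control. In parenchyma the ranges were 1029 to 2357 (without restricted 16 and 10), 2 to 316 (without control 21 and restricted 8) and 907 to 1976 (without control 18 and unlimited 3). In fat pad they were 0 to 0 in edgeR, 3093 to 6284 (without restricted 16 and control 18) and 3046 to 6973 (without unlimited 15 and control 18). Leaving out 1 number gave 8461 to 9226 between parenchyma and fat pad, and 20 to 269 (without 15 and 10), 589 to 1284 (without 4 and 8) and 0 to 48 (the highest without 8) for the interactions. In simulated data of the depth and spread of liver of unlimited against restricted, 9.23% of 1.5-fold changes were recovered, so small changes there were mostly not detectable.

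With the number as a replicate block in edgeR, and as a random block in limma voom, parenchyma against fat pad gave 8687 and 9469 genes. The interactions gave 299 and 310 for parenchyma with fat pad, 1255 and 1428 for parenchyma with liver, and 0 and 0 for fat pad with liver, where 2122 had an unadjusted p under 0.05 without a block. The labels do not say what a shared number means. After removal of group means, the mean correlation across genes of libraries with the same number was 0.14, 0.11 and 0.08 for parenchyma with fat pad, parenchyma with liver and fat pad with liver, against -0.013, -0.01 and -0.0072 for different numbers. It was over 0.1 for 7, 9 and 5 of 12 numbers, and the same number was the best match for 5, 7 and 5. This is a hint of pairing from the data, not the design, and since not every pair was over 0.1 the numbers were not taken to pair the samples.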

Other observations

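The tests on genes called in parenchyma, carried into the other tissues, were chosen after seeing the data but before their own results, and the test on left-out parenchyma pairs and the score of the parenchyma control libraries were chosen only after the result was seen.

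Genes called in parenchyma between the unlimited and restricted diets were followed in the other tissues. In fat pad, 834 of the 1084 higher genes were also higher in unlimited calves, with a median log2 fold change of 0.11, and 476 of the 654 lower genes were lower, with a median of -0.12. In liver, 396 of the 1061 higher genes were higher, with a median of -0.081, and 213 of the 601 lower genes were lower, with a median of 0.094. A diet response that fat pad may share had camera p-values of 2.58e-09 and 5.52e-09 for the higher and lower genes with the preset correlation, and 0.191 and 0.118 with an estimated correlation. In liver the higher genes moved down and the lower genes up, with p-values of 0.000344 and 0.0374 with the preset and 0.371 and 0.531 with an estimated correlation. The first reading, on the preset correlation alone, took fat pad as sharing the response and liver as excluding it. Both readings were changed after the values were seen, since neither held with an estimated correlation. The bound set beforehand, p-values over 0.05 for both sets, was not applied, as a p that misses the threshold does not exclude a small movement, and the preset p-values were under it. With genes called without 1 pair of parenchyma libraries at a time, the score of higher minus lower genes differed between the diets by 1.29 in the pairs left out (0.36 to 2.14), against 1.52 in the libraries used for the choice. It differed by 0.27 in fat pad (95% exact permutation interval -0.05 to 0.6, n = 6 each) and by -0.16 in liver (-0.52 to 0.19). The differences in fat pad and liver were 0.207 and -0.121 of the mean left-out difference, and both upper bounds lay below that mean. In liver the upper bound of 0.19 lay below every left-out difference, which argues against a response there of the size in parenchyma. The upper bounds were 1.67 and 0.528 of the lowest left-out difference, that of a single pair. Against that pair a response of 0.5 or more of that in parenchyma is not excluded in either tissue. Whether fat pad shares the response, or liver a smaller part of it, cannot be told apart from correlated noise. Of the 2 genes called lower in liver of unlimited calves, 1 was among the 601 lower genes of parenchyma, where 0.0936 would be met by chance.

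The mean log2 CPM of the higher genes minus that of the lower genes was -0.0198 ± 0.32 in restricted (SD, n = 6), 1.5 ± 0.22 in unlimited (n = 6) and 0.278 ± 0.33 in control parenchyma (n = 3). The control mean exceeded the restricted mean by 0.3, with an exact permutation p of 0.25, where 0.012 is the smallest this design can give. The genes were chosen on the restricted and unlimited libraries, so the distance between these diets is not independent evidence, and whether control parenchyma resembles restricted parenchyma stays open.

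For the counts not covered with the patterns, other splits of the same samples were refitted. For parenchyma of restricted and unlimited calves against control, 1 of 84 splits gave as many genes as the real 49 and 1881, with 10 and 5 as the highest of the others. That is the lowest share these splits can give, so chance is argued against but not excluded. The same holds for 1 of 100 splits with the real 121 genes in liver of restricted against control (highest other 8), 9032 between parenchyma and fat pad (1120), 125 and 1158 for the interactions of parenchyma with fat pad (31) and with liver (28), and 789 in parenchyma of the other diets together against control (48). In liver of unlimited against control, 2 of 100 splits gave as many as the real 68, the highest 127. That split put control 1 and 21 with unlimited 7, 9, 15 and 11, which points to a structure of the samples. The TMM factors of these libraries were 0.617 to 0.799. Those of control 2 and 18 and unlimited 3 and 6, on the other side, were 0.870 to 0.942, so the split follows the TMM factors. Whether this difference accounts for the 127 genes was not tested. In liver of unlimited against restricted, 3 of 100 splits gave as many as the real 2, the highest 9. For fat pad of unlimited against restricted and for the interaction of fat pad with liver the real count was 0 in edgeR, with 1316 and 2122 genes at an unadjusted p under 0.05, and DESeq2 called 3 and 157 and limma voom 0 and 6. With a real count of 0 all 100 splits must give as many, so the splits decide nothing there, and the highest of the others were 172 and 1. The split with 172 put fat pad 4, 10 and 16 with 7, 15 and 11, which points to a structure of the samples. The same numbers made the highest other split in parenchyma, with 3 genes, and what the structure is was not tested.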
